A study of Mus musculus with 2 samples.

How the data were processed

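The series held 2 single-cell RNA libraries of live CD45+ cells sorted from MB49 tumours, 1 per genotype label, made with the BD Rhapsody whole-transcriptome kit after enzymatic digestion at 37 degrees Celsius. The deposited matrices hold counts, which are UMIs per gene and cell barcode with no normalisation, for 31253 genes. Per the submitters' processing notes, Cell Ranger and the mm10 genome were used, with no version or role given. No barcode had fewer than 501 UMIs. Groups were taken from the genotype label, and the library labelled Lcn2-ko was compared with the wt library throughout.

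Cells were kept with at least 200 genes and at most 20% mitochondrial UMIs, which left out 82 wt barcodes and 46 of the library labelled Lcn2-ko for few genes, and 262 and 241 for mitochondrial share. Doublet scores came from Scrublet in scanpy 1.11.5, run per library at an expected rate of 0.06. The threshold chosen by Scrublet marked 1 cell per library, so the cells with the highest 4% of scores were left out instead, 319 and 312 cells, some of which also failed another limit. That rule was chosen after seeing the data. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within each library, leaving out Lcn2, Y-linked genes, Xist, and mitochondrial, ribosomal protein, immunoglobulin, T cell receptor and haemoglobin genes. Both libraries were clustered together on 30 principal components with no batch correction, 15 neighbours and the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1, giving 29 clusters.

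Clusters were named from fixed marker lists, by the class with the largest share of markers at least 2-fold higher than in other cells. Leading genes served as a check on that name. A cluster could be named with no marker among its leading genes, as clusters 14, 15 and 20 were. Limits set after seeing the data were a mean Ptprc level of 100 CPM, below which a cluster was set apart as Ptprc-low, a Cd3e level of 500 CPM in clusters with NK cell markers, and a 55% limit on the markers of a second class. Set apart as Ptprc-low were 25.1% of wt cells and 23.2% of the library labelled Lcn2-ko. Left unnamed were 5.33% and 4.93% with NK cell markers and Cd3e, and 0.784% and 0.663% with markers of more than 1 class. Another 0.757% and 0.276%, with few UMIs and no marker among the leading genes, were left unnamed too. The 5 classes with at least 100 cells in each library were compared. Neutrophils were clustered again on 1000 variable genes and 15 components at a resolution of 0.6, without 279 genes that differed at least 1.5-fold between the libraries.

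UMIs were summed over the cells of a class and scaled to CPM, that is to a class total of 1e+06. With 1 library per label no test was run and no standard error was formed. The 95% intervals are exact Poisson intervals for UMI sums, Clopper-Pearson intervals for shares, Newcombe intervals for differences of shares, and exact conditional binomial intervals for ratios. A count of 0 was read as allowing up to 3 counts. Depth was 42069099 UMIs in wt and 40959725 in the library labelled Lcn2-ko, and the neutrophil sums were 940823 and 504479 UMIs. Gene counts at a 2-fold limit were taken among genes open to naming under the rule below, so ribosomal protein genes with Rpl or Rps symbols, such as Rps19, are not in them. Fau, which encodes a ribosomal protein under another symbol, was not left out by the rule and is in them.

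The rule for named genes, the gene groups and most alternatives were fixed before the data were examined. The genes named by the rule are the extremes of these same libraries, and their intervals do not allow for that choice. The rule named, in neutrophils, monocyte-macrophages and T cells, the 12 genes with the highest and the 12 with the lowest ratio among genes with at least 50 CPM in either library and 50 UMIs over both. Lcn2, sex-linked marker genes, mitochondrial, ribosomal protein, receptor segment, haemoglobin and predicted genes were left out of it. In the other classes 4 genes per side with at least 100 CPM were named. From each gene group up to 4 members were named, those with the highest and lowest ratios and the most abundant. Members with at least 20 CPM in either library counted as measured, and each group median was also placed among 10000 random groups matched on expression.

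Alternatives covered doublets, the gene and mitochondrial limits, centring within library, resolution, scaling, thinning to 800 UMIs per cell, means over cells, and the abundance limit. Those added after seeing the data covered single top cells, cluster weights, cluster 7, a neutrophil state, cells with Y-linked UMIs and no Xist, cells outside the Ptprc-low clusters, and clustering without differing genes. Cluster weights were applied to dendritic cells last, for the values given for that class. The thinning depth was set after seeing the depths. Gene positions came from the GENCODE annotation of mm10, in which 31107 of 31253 gene identifiers were found.

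The methods were tested on simulated data. Among 200 genes given set differences, 199, 200 and 200 were placed on the right side in neutrophils, monocyte-macrophages and T cells, and the intervals held the set ratio for 96%, 97.5% and 94.5% of them. Intervals for differences of shares held the set value in 95.6% of 1000 draws. These counts were drawn from Poisson and binomial models with no spread between cells, the same models that the intervals assume. Coverage near the set level therefore follows from the draws. It does not show how the intervals do where a few cells hold most UMIs of a gene. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, on a single thread with a fixed seed. Differences for the unnamed clusters were not analysed here beyond their shares, and a few single-gene results are not reported here and were left out of the counts of alternatives.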

Results

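Single-cell RNA libraries were made from live CD45+ cells sorted from MB49 tumours, MB49 being a mouse bladder cancer line, and captured on the BD Rhapsody microwell system. The tumours grew in chimeric mice, lethally irradiated female hosts given male marrow that was wild type or lacked Lcn2. There were 2 libraries, 1 labelled wt and 1 labelled Lcn2-ko, and the question given for the series was how Lcn2, a secreted iron-siderophore-binding lipocalin of neutrophil granules, bears on the diversity and function of tumour neutrophils. The wt library held 7974 barcodes and 42069099 unique molecular identifiers (UMIs), with a median of 3574.5 UMIs per cell. The library labelled Lcn2-ko held 7788 barcodes and 40959725 UMIs, with a median of 3570 per cell. After filtering, 7398 wt cells and 7240 cells of the library labelled Lcn2-ko were compared. With 1 library per label there was no replicate check, no difference below was tested, and the 95% intervals cover counting error only. Ratios are the library labelled Lcn2-ko over wt on a log2 scale, and levels are shares of the class UMI sum scaled to 1e+06 (CPM).

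Lcn2 (ENSMUSG00000026822; mm10 chromosome 2, 32384633 to 32388252, minus strand) was counted in both libraries. In neutrophils it gave 198 UMIs (exact Poisson interval 171 to 228) in wt and 82 (65.2 to 102) in the library labelled Lcn2-ko, or 210 and 163 CPM. The log2 ratio in neutrophils was -0.37 (-0.76 to 0.01), so at this depth a difference was not resolved. In monocyte-macrophages Lcn2 was lower in the library labelled Lcn2-ko, at 25.6 against 13.9 CPM (log2 -0.88, interval -1.31 to -0.45). The neutrophil genes Retnlg (log2 -1.27), G0s2 (-1.17), S100a8 (-1.16) and S100a9 (-1.13) were among the lowest genes of that class too. Whether the Lcn2 difference there is separate from theirs was not tested. Among neutrophils with a Y-linked UMI and no Xist UMI, the type of the donor marrow, Lcn2 stood at 216 CPM in wt and 81.0 CPM in the library labelled Lcn2-ko (log2 -1.42; -2.38 to -0.56), the latter from 13 UMIs in 11 of 109 cells. A single neutrophil of the library labelled Lcn2-ko held 23 of its 82 Lcn2 UMIs, and with the top cell of each library left out the ratio was -0.77. Over all kept cells the ratio was -0.10 (-0.26 to 0.06), and it was -0.62 with each cell thinned to 800 UMIs. Of all Lcn2 UMIs, clusters low in Ptprc held 315 of 662 in wt and 406 of 604 in the library labelled Lcn2-ko. In those clusters the ratio was 0.45 (0.24 to 0.67), so the ratio over all kept cells joins them with classes where Lcn2 was lower.

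Cells with at least 1 Lcn2 UMI made up 15.7% of wt neutrophils (exact Clopper-Pearson interval 12.9 to 18.8%) and 10.4% (7.53 to 13.9%) of neutrophils in the library labelled Lcn2-ko, at median depths of 1353 and 1219 UMIs. T cells, a type that should lack Lcn2, gave 0.117% and 0.547% at median depths of 2546 and 2685 UMIs. After thinning to 800 UMIs the shares were 64 of 544 and 24 of 315 neutrophils, against 0 of 2557 and 4 of 2916 T cells, and the neutrophil difference was -4.15 points, with an interval that reached 0.0958. NK cells gave 0 of 238 in wt, which allows up to 1.26%, and 7 of 340 in the library labelled Lcn2-ko. The labels do not say which exons of Lcn2 were deleted. UMIs mark the 3' end of a transcript, so a tag outside the deleted part would be counted in both libraries, and these counts do not check the genotype label.

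**Figure D1:**
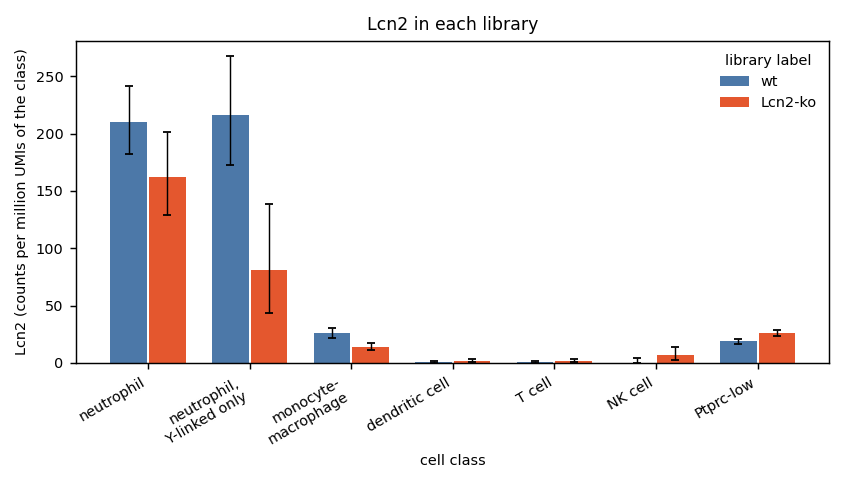
Lcn2 level in CPM (vertical axis) for each cell class (horizontal axis) in the wt and Lcn2-ko libraries; error bars are exact Poisson 95% intervals. In neutrophils the bars stand at 210 and 163 CPM, and in neutrophils with Y-linked UMIs only at 216 and 81.0 CPM.

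The gene next to Lcn2, 1110008P14Rik (chromosome 2, 32377097 to 32381938, same strand, 2694 bp away), was higher in the library labelled Lcn2-ko in 3 myeloid classes. It and Sh2d3c, also on chromosome 2, were chosen after their values were seen. In monocyte-macrophages 1110008P14Rik gave 32 and 161 UMIs (log2 2.16; 1.61 to 2.76), in dendritic cells 43 and 137 UMIs (log2 2.17), and in neutrophils 7 and 18 UMIs (log2 2.26). In clusters low in Ptprc, the gene of CD45, the log2 ratio was -0.02. Sh2d3c was lower in monocyte-macrophages (log2 -1.06).

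Donor and host origin was read from 4 Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d) and from Xist, the RNA of the inactive X chromosome, since the protocol describes male marrow in female hosts. The labels give only female, and another sentence of the protocol speaks of tumours of male and female mice, so the reading of these shares as donor or host origin rests on the hosts being female, which was not checked otherwise. Cells with Y-linked UMIs only made up 36.4% of wt neutrophils and 28.3% of those in the library labelled Lcn2-ko, a difference of -8.07 points (Newcombe interval -13.8 to -2.08). With each cell thinned to 800 UMIs the neutrophil difference was -5.20 points (-10.5 to 0.486), an interval that held 0. Cells with Xist only were 6 of 613 and 2 of 385 neutrophils. The Y-only share was 59.6% and 57.4% in monocyte-macrophages, 67.1% and 66.1% in dendritic cells, and 53.4% and 48.8% in NK cells. Y-linked UMIs did not mark donor cells cleanly. Among monocyte-macrophages with Xist, 30 of 46 in wt and 46 of 66 in the library labelled Lcn2-ko also held Y-linked UMIs. Among T cells with Xist the numbers were 37 of 431 and 47 of 560. MB49 is a male line too, and Y-linked UMIs from tumour cells were not told apart from donor ones. T cells were mixed, with Xist only in 15.4% and 17.5%, a difference of 2.18 points (0.209 to 4.13) that was 0.948 points (-0.531 to 2.41) after thinning. Most neutrophils, 61.8% and 70.9%, held neither marker, so their origin was not read.

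T cell cluster 7, led by Gzmf, Klrh1, Cd8a, Pdcd1 and Prf1, genes of cytotoxic CD8 T cells, differed most in origin among the 6 T cell clusters. Xist without Y-linked UMIs was found in 3.69% of its wt cells and 30.2% of its cells in the library labelled Lcn2-ko, a difference of 26.5 points (21.6 to 31.0). The Y-only share was 59.8% and 26.9%. After thinning to 800 UMIs the Xist-only cells numbered 3 of 267 and 70 of 483, a difference of 13.4 points. In cluster 12, with Cd4, Tnfsf11 and Tnfsf8, the Xist-only share was lower in the library labelled Lcn2-ko (15.1% against 4.71%).

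**Figure D2:**
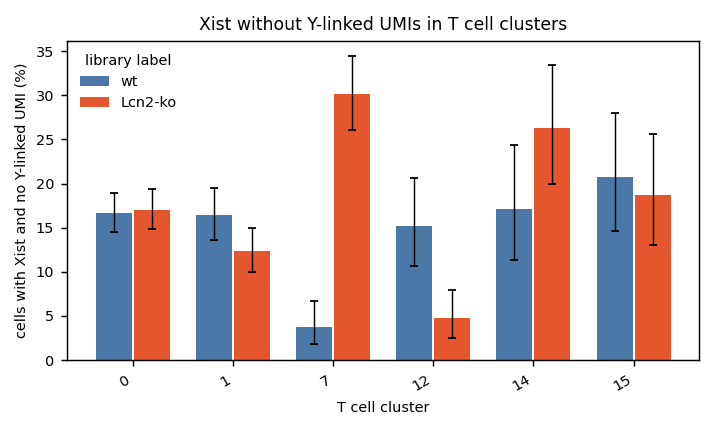
Share of cells with Xist and no Y-linked UMI (vertical axis, %) in each T cell cluster (horizontal axis, cluster number) in the wt and Lcn2-ko libraries; error bars are exact 95% intervals. Cluster 7 stands at 3.69% in wt and 30.2% in the library labelled Lcn2-ko.

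Neutrophils and dendritic cells made up smaller shares, and T cells and NK cells larger shares, of the library labelled Lcn2-ko. Neutrophils were 8.29% (7.67 to 8.94%) of wt cells and 5.32% (4.81 to 5.86%) of the library labelled Lcn2-ko, a difference of -2.97 points (-3.78 to -2.16). Dendritic cells were 10.9% and 8.19% (-2.66 points; -3.61 to -1.71), with cluster 8, marked by Xcr1 and Clec9a of cross-presenting dendritic cells, at 445 and 240 cells and cluster 11, marked by Cd209a, at 262 and 257 cells. T cells were 34.7% and 40.4% (5.73 points; 4.16 to 7.29), and cluster 7 took 10.6% and 16.5% of them (5.98 points; 4.18 to 7.77). NK cells were 3.22% and 4.70% (1.48 points; 0.849 to 2.12), and monocyte-macrophages 9.27% and 10.8% (1.51 points; 0.541 to 2.49). Mast cells or basophils (1.01% and 0.953%) and B cells (0.676% and 0.539%) had differences whose intervals held 0.

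Clusters with low Ptprc made up 25.1% and 23.2% of cells in spite of the CD45 sort; outside them the neutrophil difference was -4.14 points and that of dendritic cells -3.83 points. Shares sum to the whole of each library, so that a class can be lower because others are higher. No barcode with under 501 UMIs was in either library, and neutrophils had the lowest median depth of the 5 classes compared; how far that limit or the CD45 sort changed these shares was not measured.

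**Figure D3:**
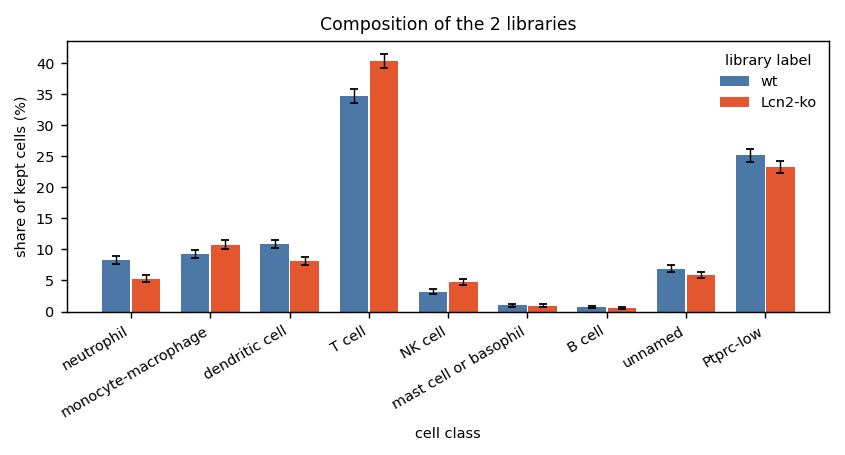
Share of kept cells (vertical axis, %) in each cell class (horizontal axis) in the wt and Lcn2-ko libraries; error bars are exact 95% intervals. Neutrophils stand at 8.29% and 5.32%, and T cells at 34.7% and 40.4%.

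In neutrophils, 28 of 2393 genes open to naming, which leaves out ribosomal protein genes with Rpl or Rps symbols but not Fau, were at least 2-fold higher and 21 at least 2-fold lower in the library labelled Lcn2-ko. The lowest ratios were those of Slc27a4, a fatty acid transport protein (80.8 against 9.91 CPM, log2 -3.03; -4.69 to -1.74), Irf7, a transcription factor of the type I interferon response (79.7 against 17.8 CPM, log2 -2.16; -3.34 to -1.16), and Ntng2 (log2 -1.81). Slc27a4 and Ntng2 lie within 5 Mb of Lcn2 on chromosome 2, and Slc27a4 was higher in dendritic cells of the library labelled Lcn2-ko (log2 1.20; 0.61 to 1.80). Other genes with low ratios were Hcst, Hsph1, Mmp12, Skap1, AU020206, Cnn2, Fau, Btbd7 and Epsti1, from -1.62 for Hcst to -1.08 for Epsti1. Mmp12 is also a leading gene of monocyte-macrophage cluster 5. A neutrophil state led by T cell genes, described below, was a smaller share of neutrophils in the library labelled Lcn2-ko. How far RNA of other cell types entered these ratios was not measured. The highest ratios were those of Camp, Ngp and Ltf, which encode secondary granule proteins made by immature neutrophils, at 4.01, 3.07 and 2.26. They were followed by Mast4 (log2 1.77), Msh3 (log2 1.71), the guanylate-binding protein gene Gbp5 (21.3 against 61.4 CPM, log2 1.53), Nrg1, Aif1, Btbd1, Mmp25, Cd177 (log2 1.27) and Emp3 (log2 1.23).

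Camp, Ngp and Ltf rested on few cells. In the library labelled Lcn2-ko, 1 neutrophil held 180 of 216 Ngp, 59 of 69 Camp, 21 of 36 Ltf, 21 of 25 Chil3 and 23 of 82 Lcn2 UMIs, and in wt 1 neutrophil held 42 of 48 Ngp and all 8 Camp UMIs. At a Leiden resolution of 2 the log2 ratio was -0.50 for Camp and -3.08 for Ngp. With each cell thinned to 800 UMIs, 8 genes were at least 2-fold higher, the ratio of Irf7 was -1.04 and that of Mast4 0.79. With the top cell left out Msh3 stood at 0.53.

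**Figure D4:**
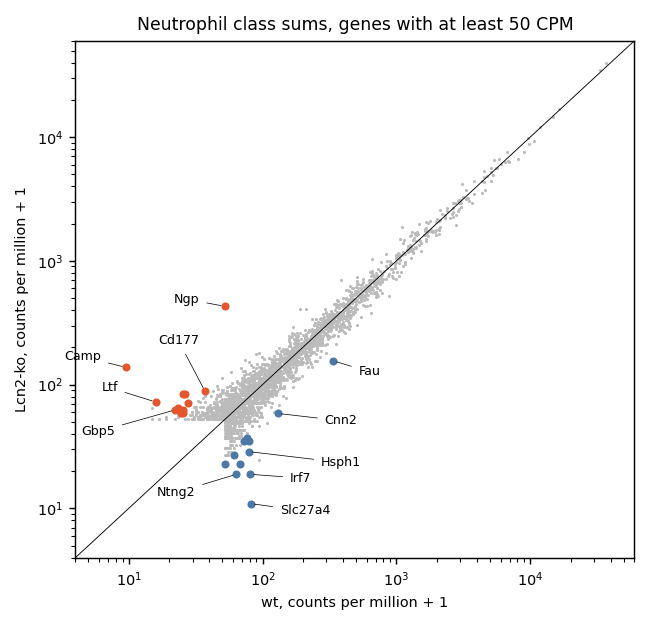
Neutrophil class sums in wt (horizontal axis) and in the library labelled Lcn2-ko (vertical axis), as CPM + 1 on log axes; each point is a gene with at least 50 CPM in either library, red and blue points are the 12 named genes with the highest and the 12 with the lowest ratios, and the line marks equal values. Ngp stands at 51.0 and 428 CPM, and Slc27a4 at 80.8 and 9.91 CPM.

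Among neutrophil gene groups, secondary granule proteins had 7 of 14 measured members at least 1.5-fold higher in the library labelled Lcn2-ko, 0 lower and 7 between, with a median log2 ratio of 0.55. With the top cell of each gene left out that median was 0.17, and its more broadly detected members Lyz2 (log2 0.01; -0.27 to 0.29) and Wfdc21 (log2 0.19; -0.11 to 0.50) did not differ beyond counting error. Interferon gamma response genes had 5 of 21 higher and 1 lower (median 0.29), with Irf1 at 208 and 408 CPM (log2 0.97; 0.68 to 1.26), Gbp5 higher and Cxcl9 at log2 -0.94 (-2.39 to 0.31). Inflammatory cytokines and NF-kB targets had 3 of 25 higher and 0 lower (median 0.13), with the adhesion receptor gene Icam1 at 387 and 694 CPM (log2 0.84; 0.63 to 1.06), Cxcl2 at log2 0.09 and the chemoattractant gene Cxcl1 at log2 -0.57. Glutathione and antioxidant defence had 2 of 20 higher and 0 lower (median 0.20), with Pgd of the pentose phosphate pathway at log2 1.09 and the cystine transporter gene Slc7a11 at 0.33. Among 10000 random groups of the same size matched on expression, the medians of these groups stood at percentiles 100, 99.5, 99.6 and 99.7 in the order given.

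Type I interferon response genes in neutrophils had 1 of 26 higher, 3 lower and 22 between (median -0.09), with Rsad2 at log2 -0.50 and Ifi47 at 0.64. Iron handling, the group closest to the known binding partner of Lcn2, had 3 of 17 higher, 1 lower and 13 between (median 0.05). The ferritin genes Fth1 and Ftl1 stood at log2 0.05 and -0.13, and Ncoa4, the receptor for ferritin turnover, at -0.72 (-1.42 to -0.07). Circulating mature neutrophil genes had 0 of 17 higher and 1 lower (median -0.05), with S100a8 at log2 0.03, S100a9 at -0.06, Cxcr2 at 0.28 and Grina at -0.79. Grina was lower in other classes too, at -0.74 in NK cells, -0.72 in monocyte-macrophages, -0.39 in dendritic cells, -0.38 in T cells and -0.64 in Ptprc-low clusters. Tumour-infiltrating neutrophil genes had 2 of 23 higher and 1 lower (median 0.03), with Nos2, the inducible nitric oxide synthase, at log2 0.93 and Siglecf at -1.74 (-3.73 to -0.21). The medians of these groups stood at percentiles 9.98, 68.7, 18.9 and 78.1 in the order given.

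MHC class II presentation in neutrophils had 0 of 9 higher and 2 lower (median -0.33, percentile 2.595), with Cd74 at log2 -0.37, H2-Ab1 at -0.33 and H2-DMb2, with 30 and 2 UMIs, at -3.01. By means over cells that median changed sign, and with cells thinned so did H2-Ab1. A neutrophil state led by T cell genes such as Cd3g, Thy1 and Lck was 9.79% of neutrophils in wt and 5.97% in the library labelled Lcn2-ko, and without it H2-Ab1 stood at log2 0.04. Nkg7 (log2 -1.04) and Gzma (log2 -3.49), genes of cytotoxic lymphocytes, stood at 0.22 and 1.28 in neutrophils when no cell was left out as a doublet.

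Neutrophils fell into 7 states after 279 genes that differed between libraries were left out of the clustering. State 0, led by Atp6v0d2, Gpnmb, P4ha1, Inhba and Nos2, held 18.4% (15.4 to 21.7%) of wt neutrophils and 26.8% (22.4 to 31.5%) of those in the library labelled Lcn2-ko, a difference of 8.32 points (3.02 to 13.8). State 4, led by Cd93, Cxcl3, Fpr1 and Thbs1, held 86 of 613 and 40 of 385 neutrophils (-3.64 points; -7.63 to 0.635). State 5, led by the interferon-induced genes Ifit2, Ifit3, Rsad2 and Cxcl10, held 10.4% and 10.1%. State 3, with Ifitm6, Hp and Wfdc21, held 13.4% and 12.5%, state 1, with Usp1, P2rx7 and Cebpd, 18.8% and 17.1%, and state 2, with Nr4a2, Il23a, Mmp9 and Icam1, 15.2% and 17.1%. In 1 random division of wt neutrophils alone into smaller groups of equal size, the largest difference of a state share was 7.78 points. With 50 genes set to differ it was 8.76 points when they were kept in the clustering. It was 7.77 points with the genes found to differ left out. A single division gives no range of such differences. The state 0 difference was 2.69 points when the differing genes were kept, and that of state 4 was 2.79 points at a mitochondrial limit of 10%, the only other clustering tried in which state 4 was matched.

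In monocyte-macrophages, 0 of 3165 genes open to naming were at least 2-fold higher and 12 at least 2-fold lower in the library labelled Lcn2-ko. The inducible heat shock genes Hspa1a (1284 against 386 CPM, log2 -1.73) and Hspa1b (993 against 288 CPM, log2 -1.78) had the lowest ratios; their sequences are near-identical, so the split of counts between them is uncertain. Isg15, an interferon-induced ubiquitin-like modifier, stood at 389 and 164 CPM (log2 -1.24; -1.36 to -1.13), and the chemokine gene Ccl22 at log2 -1.37. Isg15 also stood at -0.76 in neutrophils, -0.70 in T cells, -0.57 in dendritic cells, 0.01 in NK cells and -0.58 in Ptprc-low clusters. The neutrophil genes Retnlg (log2 -1.27), S100a8 (log2 -1.16), S100a9 (log2 -1.13) and G0s2 (log2 -1.17) were lower, and S100a8 UMIs were in 228 of 686 and 172 of 781 of these cells, at median depths of 6165.5 and 5734 UMIs, against 2.57% and 2.09% of T cells. Hes1, Hsph1, Xcl1 and Lpl completed the lowest genes. The highest were Ly6i (log2 0.90), the chemokine gene Ccl24 (232 against 418 CPM, log2 0.85), Nos2 (115 against 206 CPM, log2 0.84), the arginase gene Arg1 (358 against 619 CPM, log2 0.79; 0.70 to 0.87), Ly6a and Fn1, and lower down Cnn3, Ppp1r10, Srxn1, Cemip2, Ocstamp and Col1a1. Cnn3, Srxn1, Nos2 and Col1a1 were also leading genes of Ptprc-low clusters, where Nos2 stood at log2 0.64, Srxn1 at 0.41, Cnn3 at -0.06 and Col1a1 at -0.01, and Nos2 stood at 0.97 in T cells. With cells thinned to 800 UMIs, Ly6i stood at 0.26, Nos2 at 0.49, Retnlg at -0.75 and Ccl22 at -2.46, and by means over cells Nos2 stood at 0.33 and Retnlg at -0.25.

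Among monocyte-macrophage groups, tissue dissociation and heat shock genes had 0 of 24 higher and 6 lower (median -0.30, percentile 0), with Zfp36 at log2 -0.26 and Egr2 at 0.23. Type I interferon response genes had 0 of 23 higher and 4 lower (median -0.26, percentile 0), with Cxcl10 at log2 -0.52. Rsad2 of that group stood at log2 -0.45 and at 0.06 with cells thinned to 800 UMIs, where the group median was -0.05. Interferon gamma response genes had 26 of 26 between (median 0.09, percentile 98.2), with Gbp2 at log2 0.53. Chemokines had 1 of 19 higher and 5 lower (median -0.08, percentile 0.415), Ccl3 and Ccl4 both at log2 -0.79. Alternative activation genes had 3 of 16 higher and 2 lower (median 0.10, percentile 98.16), with Irf4 at log2 -0.78. Inflammatory monocyte genes had 2 of 15 higher and 0 lower (median 0.15, percentile 99.7), with Thbs1 at log2 0.55, and the monocyte-like cluster 13 held 159 and 226 of the class's cells. Complement and resident macrophage genes had 11 of 11 between (median -0.23, percentile 0), with Mertk at log2 -0.49 and C1qc at -0.06, or 0.14 after thinning. MHC class II genes had 12 of 12 between (median 0.01, percentile 35.9), and so did iron handling genes, 22 of 22.

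In T cells, 1 of 3471 genes open to naming was at least 2-fold higher and 2 were at least 2-fold lower in the library labelled Lcn2-ko. Gzmf, a granzyme gene, gave 160 and 1450 UMIs (20.9 against 156 CPM, log2 2.90; 2.67 to 3.15). Gzmf is a leading gene of cluster 7, and without that cluster its ratio was 1.30. Gzmc stood at log2 0.98 and at 0.25 without cluster 7, and its sequence is close enough to that of Gzmf to leave the split of counts uncertain. The pore-forming protein gene Prf1 stood at log2 0.76, or 0.43 without cluster 7. Nmrk1, Plac8, Klre1, Serpinb9, Fcer1g, Zyg11b, Irf8, Abcb1b and Il12rb2 followed, from 0.94 for Nmrk1 to 0.62 for Il12rb2. Their ratios without cluster 7 are not given here, so a part from the larger share of that cluster is open. The lowest ratios were those of Hspa1a (885 against 256 CPM, log2 -1.79) and Hspa1b (log2 -1.78), then Fau (log2 -0.97), Hspb1, Bag3, Hsph1, Ubtf, the transcription factor gene Batf (log2 -0.76), Ramp1, Qsox1, Myc (log2 -0.62) and Dnajb1.

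Cytotoxic effector genes in T cells had 3 of 21 higher and 18 between (median 0.06, percentile 96.6), with granzyme B gene Gzmb at log2 0.34, Ccl5 at 0.06 and Eomes at -0.53. That median was 0.000891 when the T cell clusters had the same weight in both libraries. Exhaustion genes had 1 of 21 lower and 20 between (median -0.08, percentile 6.58), with the checkpoint receptor gene Lag3 at log2 0.50 and Ctla4 at -0.25. Regulatory T cell genes had 17 of 17 between (median -0.16, percentile 0.04), with Il10 at log2 -0.54. The Foxp3 cluster held 1129 of 2565 T cells in wt and 1117 of 2925 in the library labelled Lcn2-ko, a smaller share of T cells. Of all kept cells it was 15.3% in wt and 15.4% in the library labelled Lcn2-ko. Helper cytokines and regulators had 1 of 10 lower (median -0.17, percentile 1.31), the member being Il17a (44.7 against 24.1 CPM, log2 -0.89; -1.14 to -0.65), found in 32 and 30 cells, and Gata3 stood at log2 -0.16, or 0.03 after thinning. Naive and memory genes had 1 of 14 lower (median -0.02, percentile 58.1), the member being Id3 (log2 -1.02). Cell cycle genes had 26 of 26 between (median -0.01, percentile 52.55).

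In dendritic cells the lowest genes were Hspa1a (log2 -1.63), Hspa1b (log2 -1.43), Bag3 (log2 -1.32) and Dnajb1 (log2 -1.28), and the highest Ly6a (201 against 407 CPM, log2 1.01), Plac8 (log2 0.95), Ifitm1 (log2 0.81) and Arap2 (log2 0.75). Inflammatory monocyte genes had 4 of 10 higher and 0 lower in this class (median 0.44, percentile 100), with Plac8 among them. The Xcr1 cluster made up 445 of 803 and 240 of 593 dendritic cells, and with clusters weighted alike that median was 0.26, Arap2 stood at 0.44, Ifitm1 at 0.58, Plac8 at 0.74 and Ly6a at 0.83. In NK cells the lowest were Hspa1a (log2 -1.63), Hspa1b (log2 -1.53), Dnajb1 (log2 -1.06) and Pld3 (log2 -0.87), and the highest Ly6a (log2 1.08), Pkp3, Klf4 and Ly6c2. Chemokines in NK cells had 5 of 9 higher and 1 lower (median 0.59, percentile 100), with Ccl5 at 1073 and 1609 CPM (log2 0.59; 0.47 to 0.71), Ccl3 at log2 -1.08 and Ccl4 at -0.37 (-0.64 to -0.10). The higher members included Cxcl9, with 9 and 33 UMIs of which 17 were in 1 cell, Cxcl1, with 15 and 43 UMIs, and Cxcl10, with 34 and 86 UMIs of which 30 were in 1 cell. The fixed lists of macrophage, monocyte and MHC class II genes also had medians above 0 in NK cells, at 0.46 for MHC class II presentation (percentile 100), 0.31 for classical activation (99.1), 0.26 for complement and resident macrophage genes (88.5), 0.23 for alternative activation (96.7), 0.22 for inflammatory monocyte genes (99.7) and 0.11 for lipid-associated macrophage genes (88.4). Cxcl1, Cxcl10 and these medians were chosen in this class after their values were seen. Tissue dissociation and heat shock genes had 6 of 24 lower and 0 higher in both classes. In neutrophils that group had 1 of 24 lower, and Hspa1a and Hspa1b stood at 0.18 and 0.05, or -0.09 and -0.39 with cells thinned.

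**Figure D5:**
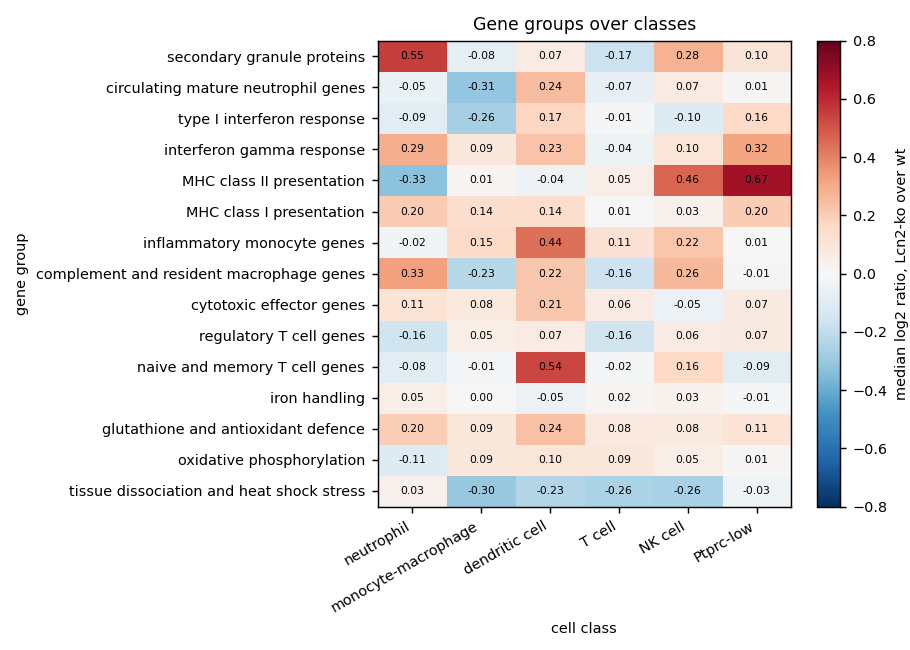
Median log2 ratio, Lcn2-ko over wt, of the measured members of 15 gene groups (vertical axis) in 6 cell classes (horizontal axis); the colour scale and printed values give the median. Secondary granule proteins stand at 0.55 in neutrophils, and tissue dissociation and heat shock genes at -0.30 in monocyte-macrophages.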

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

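The tests of explanations below were chosen only after the results were seen, except the thinning of cells, which was planned.

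Some signals lay outside the comparisons that the series was made for. In Ptprc-low clusters, which the CD45 sort should have left out, Lcn2 gave 406 UMIs in the library labelled Lcn2-ko and 315 in wt. The gene 1110008P14Rik, next to Lcn2, gave 161 UMIs in monocyte-macrophages of the library labelled Lcn2-ko and 32 in wt. Rps19, a ribosomal protein gene outside the rule for named genes, gave 1866 UMIs in T cells of the library labelled Lcn2-ko and 3181 in wt. Cd74, the MHC class II invariant chain gene, gave 9329 UMIs in Ptprc-low clusters of the library labelled Lcn2-ko and 6464 in wt. None of these differences was tested.

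Lcn2 UMIs were present in neutrophils of the library labelled Lcn2-ko, at 163 CPM. Free RNA as the whole source is argued against, since Lcn2 stood 88.92-fold (52.3 to 160) higher in neutrophils than in T cells of that library. Host neutrophils as the whole source are argued against by 11 neutrophils with Lcn2, a Y-linked UMI and no Xist UMI. That holds only if the hosts were female, as the protocol describes, and a Y-linked UMI marks a donor cell. MB49 is a male line too. Among neutrophils with Xist, 5 of 11 in wt and 1 of 3 in the library labelled Lcn2-ko also held Y-linked UMIs. Tags of a transcript left by an altered locus in donor cells may account for the Lcn2 UMIs and stay open. The gene 1110008P14Rik was higher in monocyte-macrophages (log2 2.16, interval 1.61 to 2.76). The deleted exons are not given, so an altered locus and an intact gene in some donor cells cannot be told apart.

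Cluster 7, with Gzmf, Prf1 and Cd8a, was larger in the library labelled Lcn2-ko and more often held Xist without Y-linked UMIs. Depth is argued against by the difference of 13.37 points (9.81 to 16.9) after thinning. Free RNA of host cells as the whole source, raising all clusters alike, is argued against by the other T cell clusters. Before thinning, their differences ran from -10.43 points (-16.1 to -5.20) in cluster 12 to 9.14 (-0.127 to 17.9) in cluster 14. Clusters 0, 1 and 15 stood at 0.358, -4.04 and -2.03 points, against 26.5 (21.6 to 31.0) in cluster 7. A smaller part from free RNA is not excluded, because host shares could differ between clusters too. A few expanded host clones may account for the pattern and stay open, because 21 of 484 cells held a T cell receptor beta V gene UMI, too few to count clones. The marrow genotype and the number of radioresistant host T cells in each mouse are open too and were not tested.

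The heat shock genes Hspa1a and Hspa1b and the ribosomal genes Fau, Rps19 and Rplp1 were lower in the library labelled Lcn2-ko in most classes compared, with 23 of 25 ratios below 0 and a median log2 ratio of -1.13; in neutrophils Hspa1a and Hspa1b stood at 0.18 and 0.05. GC content and transcript length, as trends over all genes, are argued against by a median of -1.131 after both trends were removed. A greater weight of deep cells is argued against by -1.109 after thinning. The first step removes only what many genes share, and thinning only evens the weight of cells. A technical effect particular to these genes was therefore not tested. Marrow genotype acting within marrow-derived cells is argued against for Fau, Rps19 and Rplp1 by a median of -1.015 in Ptprc-low clusters. That holds only if the cells of those clusters did not come from the marrow. Their origin was not checked, since Y-linked UMIs do not separate tumour from donor cells there. For Hspa1a and Hspa1b the Ptprc-low median was -1.192 against -1.63 over the 5 classes, which leaves a part from genotype open. Handling of the tumours and libraries could also account for it, and with 1 library per label it cannot be told apart from genotype.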

How the results depend on the processing

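The alternatives with Y-linked UMIs only, clusters weighted alike, each gene's top cell left out, cells outside Ptprc-low clusters, without cluster 7, without neutrophil state 6, and clustered without differing genes were chosen after seeing the data; the others were planned. No paired analysis was possible because each label had 1 library, and no library could be left out in turn. Of 208 values for the 26 main results, 178 stayed within their limits, 30 moved and 0 reversed, a change of sign being counted as reversed where the interval of the reported value left out 0. State 4, whose interval held 0, changed sign and is among the moved values. Of 3975 values for named genes, 3632 stayed, 312 moved and 31 reversed, and of 994 for gene group medians, 898 stayed, 84 moved and 12 reversed. Those counts are for genes and gene groups of neutrophils, monocyte-macrophages and T cells, with cluster weights alone for dendritic cells. Genes and gene groups of NK cells and Ptprc-low clusters are not in them. Centring within library, median-ratio scaling and clustering without differing genes reversed no value and moved no main result. The cause was not tested unless stated. Depth limits what neutrophils show, at a median of 1353 and 1219 UMIs, and genes at few UMIs rest on few cells. Scaling and means over cells gave no value for shares of cells. State 4 was matched at the mitochondrial limit of 10% alone, and state 0 in every other neutrophil clustering tried, so the rest gave no value.

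At a Leiden resolution of 2, the neutrophil Lcn2 log2 ratio went from -0.37 to -0.85, Camp from 4.01 to -0.50, Ngp from 3.07 to -3.08, and the secondary granule median from 0.55 to 0.099. In cells with Y-linked UMIs only, neutrophil Lcn2 stood at -1.42. With at least 10 UMIs over both libraries in place of the abundance limit, which adds genes with few counts, genes at least 2-fold higher and lower numbered 184 and 174 in T cells (from 1 and 2), 167 and 319 in monocyte-macrophages (from 0 and 12), and 358 and 510 in neutrophils (from 28 and 21). With at least 500 genes per cell, 1 gene was higher in monocyte-macrophages and 33 were lower in neutrophils. At a mitochondrial limit of 10% the neutrophil state 4 difference went from -3.64 to 2.79 points, and with the differing genes kept the state 0 difference went from 8.32 to 2.69 points. Outside Ptprc-low clusters the share differences were -3.83 points for dendritic cells (from -2.66) and -4.14 for neutrophils (from -2.97).

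With each cell thinned to 800 UMIs, Lcn2 over all cells went from -0.10 to -0.62, and the cluster 7 Xist difference from 26.5 to 13.4 points, fewer UMIs per cell giving fewer cells with Xist. In T cells thinning gave 0.0214 for Atf3 (from -0.27), 0.0262 for Gata3 (from -0.16), 0.00548 for Gpx1 (from -0.18) and 0.0541 for the secondary granule median (from -0.17). In monocyte-macrophages thinning gave 0.00726 for Btg1 (from -0.06), 0.14 for C1qc (from -0.06), 0.0218 for Cd74 (from -0.05), -0.0271 for Ctsc (from 0.09), 0.0523 for Hp (from -0.30), -0.67 for Ifng (from 0.51), -0.19 for Nkg7 (from 0.16), -0.13 for Psmb8 (from 0.10), 0.0640 for Rsad2 (from -0.45), -0.00273 for Tuba1b (from 0.14) and -0.24 for the dissociation and heat shock median (from -0.30), with 9 genes higher and 27 lower. In neutrophils it gave 0.0513 for Ccl17 (from -2.37), 0.37 for Ccr2 (from -1.32), 0.0639 for H2-Ab1 (from -0.33) and -0.0117 for Il1b (from 0.05), with 8 genes higher. Ccl17 gave 29 UMIs in wt and 0 in the library labelled Lcn2-ko, so both of its ratios are upper bounds at 3 counts, and its change of sign says nothing about direction.

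With clusters weighted alike, T cell medians stood at 0.0107 for NADPH oxidase (from -0.04), 0.0638 for circulating neutrophil genes (from -0.07), 0.000872 for complement (from -0.16), 0.0519 for secondary granule proteins and 0.000891 for cytotoxic genes (from 0.06). Without cluster 7, T cell Hmgb2 stood at 0.00659 (from -0.05), the circulating neutrophil median at 0.00326, and 0 genes were 2-fold higher, because Gzmf is a gene of that cluster and fell under the abundance limit.

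With each gene's top cell left out, neutrophil Lcn2 stood at -0.77, the secondary granule median at 0.17 in neutrophils and 0.13 in T cells, and monocyte-macrophage Ifng at -0.0567, and 17 genes were higher in neutrophils. By means over cells, Lcn2 over all cells stood at -0.45, the neutrophil MHC class II median at 0.0349 (from -0.33), the tumour-infiltrating median at -0.00441 (from 0.03), H2-Ab1 at 0.0166, and in monocyte-macrophages C1qc at 0.0241, Ctsb at 0.0169 (from -0.07), Hilpda at -0.00828 (from 0.10) and the hypoxia median at -0.00224 (from 0.08), with 1 gene higher. With no cell left out as a doublet, the T cell secondary granule median was 0.0690, neutrophil Gzma 1.28 (from -3.49) and Nkg7 0.22 (from -1.04), with 18 genes higher and 12 lower in neutrophils. Without neutrophil state 6, the tumour-infiltrating median was -0.0169, Ccr2 0.75, H2-Ab1 0.0370, Il1b -0.0204 and Nkg7 0.33.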

Other observations

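Values below were examined only after they had been seen.

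Clusters low in Ptprc made up 25.1% of wt cells and 23.2% of the library labelled Lcn2-ko. Over all of them MHC class II presentation had 6 of 8 measured members at least 1.5-fold higher and 0 lower (median 0.67, percentile 100 among random groups), with H2-Aa, a class II alpha chain gene, at 381 and 640 CPM (log2 0.75), H2-Ab1 at log2 0.58 and the invariant chain gene Cd74 at 385 and 590 CPM (log2 0.62; 0.57 to 0.66). Interferon gamma response genes had 4 of 25 higher and 0 lower (median 0.32, percentile 100), with the T cell chemoattractant gene Cxcl9 at 155 and 320 CPM (log2 1.05; 0.98 to 1.12), Gbp2 at log2 0.87 and Igtp at 0.78. Nos2 stood at 416 and 650 CPM (log2 0.64), and Ifng gave 25 and 64 UMIs (log2 1.44). MHC class I presentation had 18 of 18 between (median 0.20, percentile 100), and the keratin genes Krt8 and Krt18 stood at log2 -0.03 and 0.06. Gbp2, Igtp, Ifng, Krt8 and Krt18 were chosen after their values were seen.

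The same genes were compared within the 3 largest Ptprc-low clusters, numbers 2, 3 and 6. There Cd74 stood at log2 0.94, 0.64 and 0.55 and Cxcl9 at 1.27, 1.03 and 0.98. The smaller clusters were not alike. In cluster 26, with 19 and 25 cells and Col1a2, Rgs5, Igfbp7 and Postn among its leading genes, Cd74 stood at log2 -1.23 (-1.92 to -0.56), H2-Aa at -1.56 and H2-Ab1 at -1.09, and Cxcl9 at 3.49 from 2 and 37 UMIs. In clusters 16, 23 and 25, H2-Aa stood at log2 0.63 (0.07 to 1.18), 0.38 (0.11 to 0.65) and -0.51 (-1.38 to 0.30), and Cxcl9 at -0.18 (-1.11 to 0.72), -0.72 (-1.48 to -0.01) and 0.56 (-0.99 to 2.05). Cd74 stood at 485 CPM in both libraries in cluster 16, and at log2 0.12 (-0.12 to 0.36) in cluster 23 and 0.43 (-0.14 to 1.00) in cluster 25. Over all Ptprc-low clusters, the fixed lists of macrophage and monocyte genes had medians of 0.47 for classical activation (percentile 100), 0.11 for lipid-associated (99.8), 0.08 for alternative activation (84.6), 0.01 for inflammatory monocyte (44.9) and -0.01 for complement and resident macrophage genes (59.0). Those of T cell genes were 0.15 for exhaustion (99.7), 0.07 for cytotoxic effector (95.3), 0.07 for regulatory T cell (90.7), -0.09 for naive and memory (8.585) and -0.23 for helper genes (0.995). Single immune genes could differ more than these medians, with Gzmb at log2 0.78 (0.58 to 0.98), Trem2 at 0.67 and Ccl5 at 0.61. Lyz2 stood at -0.01 and Ccl4 at -0.31. These lists and genes were chosen after their values were seen. MB49 is a male line, so Y-linked UMIs do not separate tumour from donor cells in these clusters.

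Mast cells or basophils held Xist without Y-linked UMIs in 22 of 75 wt cells and 9 of 69 cells of the library labelled Lcn2-ko, a difference of -16.3 points (-28.9 to -2.83). At median depths of 5368 and 4409 UMIs this did not hold once cells were thinned to 800 UMIs, with 7 of 75 and 6 of 68 cells, a difference of -0.510 points (-10.4 to 9.77). The libraries shared 4 barcodes, against 1.10 expected by chance from the barcode pieces seen. Within 5 Mb of Lcn2, 2 of 51 genes counted differed at least 2-fold in monocyte-macrophages, against 17 of 5831 elsewhere. The counts were 2 of 45 against 24 of 5708 in dendritic cells and 2 of 21 against 54 of 2897 in neutrophils. They were 1 of 43 against 35 of 4981 in NK cells and 0 of 54 against 5 of 6138 in T cells. In Ptprc-low clusters they were 0 of 64 against 15 of 6573. The genes behind the neutrophil count were Ntng2 and Slc27a4. The gene next to Lcn2, 1110008P14Rik, is not in that count, although it was more than 2-fold higher in neutrophils, on few UMIs. The abundance limit for these counts was thus not the CPM limit for gene group members alone.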
